A study of Mus musculus with 18 samples.

How the data were processed

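RNA was sequenced from Lang+ and Lang- migratory dendritic cells sorted from ear-draining lymph nodes of LangGFP C57BL/6J mice that were untreated, given MC903 or given OVA, in 18 libraries, 3 for each of the 6 groups. Per the labels, nodes were digested with collagenase D and DNase, cells were stained for B220, CD11c and I-A/I-E with propidium iodide, RNA was purified with RNeasy Micro columns, and libraries were made with SMART-Seq v4 and Nextera XT from polyadenylated RNA. The stain held no T cell marker. The table deposited by the authors holds raw read counts for 33012 Ensembl genes. The submitters' notes name bcl2fastq 2.17.1.14, STAR 2.5.3a, HTSeq 0.6.1p1 and the mouse genome mm10, and the strand setting, the counting mode and the annotation release are not given in the sources used here. All 33012 gene IDs matched a symbol and coordinates in GENCODE M21 (GRCm38), and 35 IDs share a symbol with another. The genes mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and Ahsp were not analysed here.

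Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalization, filterByExpr by group, estimateDisp and glmQLFit with robust settings, and glmQLFTest. The filter kept 16729 genes, 50.7% of the table, and the common biological coefficient of variation was 0.202. A single fit of 6 group means over the 18 libraries served 11 comparisons: each treatment against untreated and against the other treatment within a population, Lang+ against Lang- within each treatment, and 2 interactions. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of the F statistic. Same-number libraries of the same treatment exceeded a correlation of 0.1, the threshold set for pairing, in 3 of 9 pairs (-0.065 to 0.165), so a replicate block was fitted only as an alternative. Their median was 0.073, against -0.0405 for other numbers, and 14 of 18 libraries correlated best with their own number, a hint of pairing from the data, not from the design. Across replicates of a group the spread exceeded counting error, with chi-squared per degree of freedom between 12.4 and 40.6.

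The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The 37 lists held 22 of biology, 2 of quality and 13 of markers of other cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a comparison, with an estimated correlation and with fry, which asks whether a list moves one way and does not compare it with other genes. Of 407 tests of a list in a comparison, 127 passed with the preset correlation, 3 with an estimated correlation, all 3 of them the cDC2 genes in the Lang+ against Lang- comparisons, and 136 with fry, 99 of these shared with camera. The named genes were the 10 largest rises and falls in each of 5 main comparisons, or 5 each way in the others, among called genes with at least 10 CPM in the higher group and no overlap between libraries. Predicted genes, pseudogenes and immunoglobulin and T cell receptor segments were left out of this ranking, 51, 0, 54, 29 and 95 in the main comparisons. Up to 4 members of each list with the smallest p and 11 genes fixed in advance were eligible besides.

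A fold against a group with no count was computed against a floor of 3 counts over the group and is given as a lower bound. The sort was checked on log2(CPM + 1) of Cd207 with exact two-sided permutation tests. Calls were tested on simulated data with changes of 2-fold and 4-fold set in 100 genes each, where edgeR recovered 85% and 99% with 5 false calls, DESeq2 1.42.0 89% and 99% with 21, and limma-voom 82% and 99% with 4. The changed genes were drawn from those above 3 CPM in untreated Lang+ libraries, and all 18 libraries were simulated from the untreated Lang+ means. The alternatives were DESeq2 size factors, no filter on low counts, at least 10 CPM in 3 libraries, the DESeq2 Wald test, limma-voom with quality weights, only the compared groups, replicate blocks, 2 stricter thresholds and leaving out each library. A T cell score of each library, the mean log2 CPM of the T cell markers, was added as a covariate after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served the remaining steps.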

Results

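RNA of 2 populations of migratory dendritic cells was sequenced from the lymph nodes that drain the mouse ear. Lang+ and Lang- cells were sorted from LangGFP C57BL/6J mice, which carry a green fluorescent reporter of langerin. Langerin, encoded by Cd207, is a C-type lectin of Langerhans cells and of part of the conventional type 1 dendritic cells (cDC1). The mice were untreated, given MC903 (calcipotriol, a vitamin D analogue) or given a treatment labelled LMP/OVA, here OVA, where the labels do not expand LMP, and the series names these treatments as 2 conditions of atopic dermatitis. None of the 6 groups was given LMP alone or a vehicle alone. Effects named here as those of OVA or MC903 therefore cannot be told apart from effects of LMP or of a vehicle. Each of the 6 groups of population and treatment held 3 replicate libraries, 18 in all, and the labels do not say whether each replicate is a separate animal, so p-values measure the spread between these samples. Total counts per library, in units of 1e+06, ran from 17.82 to 29.71 with a median of 22.04, and 13792 to 15474 genes per library had at least 10 counts. In the library with the smallest normalized size 1 count equals 0.0558 CPM (counts per 1e+06 of normalized library size), and the floors used for folds cover counting error only. Log2 CPM of replicates correlated across genes with Pearson's r between 0.986 and 0.994, where genes are not independent replicates. The first principal component, with 42.8% of the variance, separated Lang+ from Lang- libraries, and the second, with 11.2%, separated MC903 libraries from the others. Unless stated otherwise, gene values are log2 fold changes ± SE from edgeR, with p adjusted over 16729 tested genes. CPM values are means ± SD of 3 libraries.

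**Figure D1:**
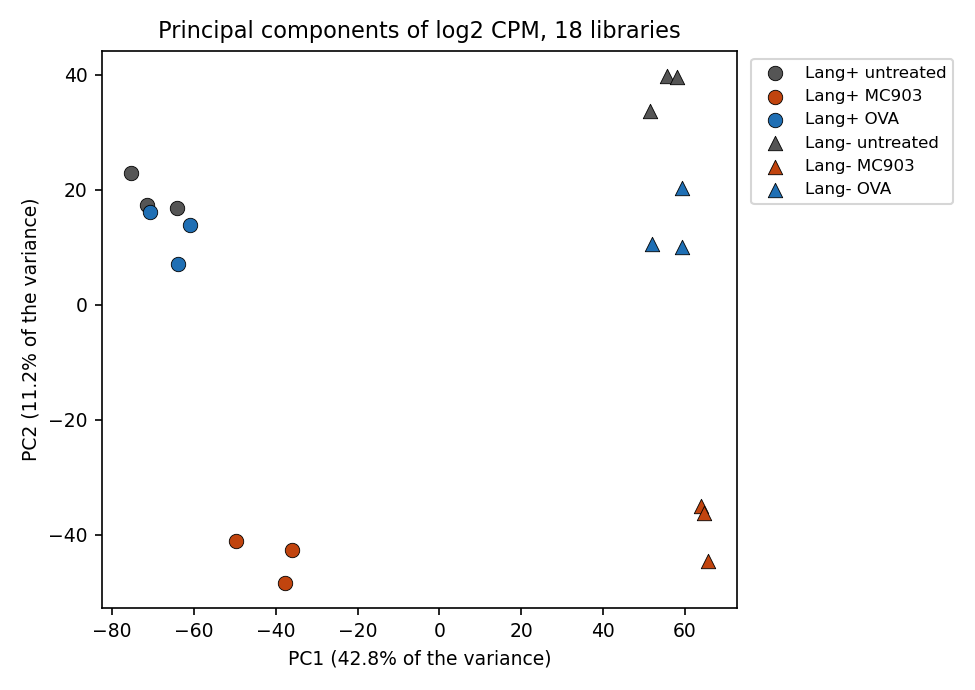
Principal components of log2 CPM over the 18 libraries, with PC1 (42.8% of the variance) on the x axis and PC2 (11.2%) on the y axis, each point 1 library, circles Lang+ and triangles Lang- cells, and colours the treatment. MC903 libraries of both populations lie lowest on PC2.

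The sort was checked on Cd207 (ENSMUSG00000034783, chromosome 6, 83671215 to 83677857, mm10). Cd207 averaged 89.4 ± 36.0 CPM in untreated Lang+ cells, 20.6 ± 2.03 with MC903 and 77.7 ± 7.92 with OVA. In Lang- cells it averaged 0.2997 ± 0.199, 0.278 ± 0.0753 and 0.0287 ± 0.0498 CPM. The difference between populations in log2(CPM + 1) was 6.06 in untreated mice, 4.08 with MC903 and 6.25 with OVA, each with p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 libraries allow. Over all libraries, 9 against 9, it was 5.46 with p = 4.1e-05 in the same exact test, also the smallest possible, and all 9 Lang+ libraries lay above all 9 Lang- libraries. The count table held 0 genes named GFP or EGFP.

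**Figure D2:**
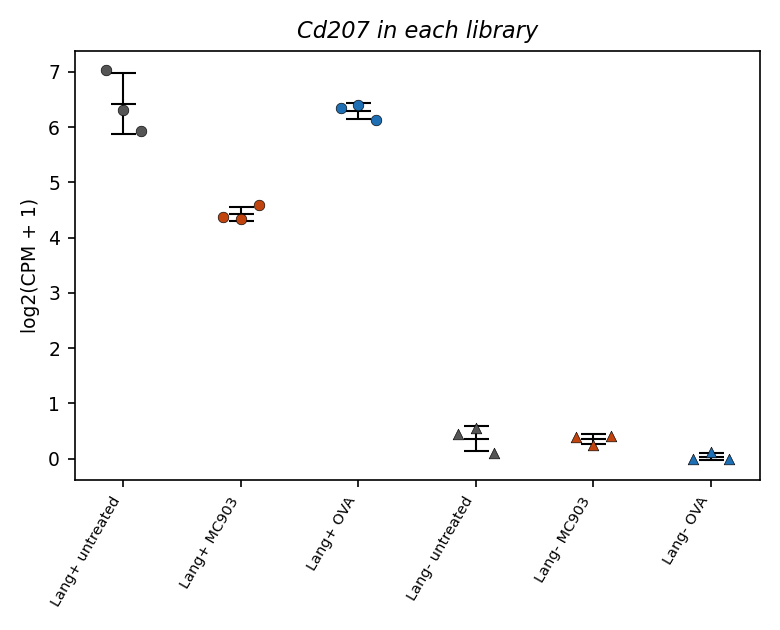
Cd207 expression as log2(CPM + 1) on the y axis for each of the 18 libraries, by group on the x axis, with the mean and SD of 3 libraries. Group means in Lang+ cells were 6.42 untreated, 4.43 with MC903 and 6.29 with OVA, and those in Lang- cells were 0.37, 0.35 and 0.04.

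Untreated Lang+ cells differed from untreated Lang- cells in Cd207, Epcam and Mfge8 on one side, and in class II antigen presentation, type 2 dendritic cell (cDC2) and proliferation genes on the other (3 libraries per group). Of 16729 genes, 5323 differed, 2541 higher and 2782 lower in Lang+ cells, with 1160 and 1229 at 2-fold or more. Among genes higher in Lang+ cells were Epcam, an epithelial adhesion molecule, at 143 ± 3.91 against 16.4 ± 2.70 CPM, and Mfge8, a bridging protein for apoptotic cells, at 2858 ± 471 against 283 ± 23.1 CPM. Among genes lower in Lang+ cells were H2-Ab1, a class II chain, at 1929 ± 130.0 against 8699 ± 1030.0 CPM, and Aldh1a2, a retinoic acid synthesising enzyme, at 8.84 ± 3.03 against 252 ± 12.0 CPM.

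The largest differences toward Lang+ cells included 3 genes with no count in the untreated Lang- libraries. Against a floor of 3 counts over the group, the adrenergic receptor Adra1a was at least 522-fold higher, Syt9, a synaptotagmin, at least 268-fold and Atp8b1, a phospholipid flippase, at least 248-fold. Cd207 (8.25 ± 0.36, adjusted p = 5.43e-12), Tnfaip8l3 (8.06 ± 0.58), Pkp1 (7.93 ± 0.63) and Tcim (7.43 ± 0.35) followed, where Pkp1 encodes the desmosomal protein plakophilin. Fam189a2 (7.03 ± 0.28), Tjp1 (6.71 ± 0.52) and Pcsk6 (6.68 ± 0.73) completed the highest 10, where Tjp1 encodes a tight junction scaffold and Pcsk6 a proprotein convertase. On the lower side Tmprss11d, a transmembrane protease, averaged 0.0463 ± 0.0802 against 10.3 ± 2.07 CPM. The macrophage elastase gene Mmp12 (-7.26 ± 1.13), the lectin Cd209e (-6.59 ± 0.55), the GDNF family receptor Gfra2 (-6.41 ± 0.27) and Stra6l (-6.15 ± 0.49) were lower in Lang+ cells. Cyp2ab1 (-5.77 ± 0.58), the Wnt antagonist Dkk2 (-5.74 ± 0.40), the lectin Mgl2 (-5.62 ± 0.41), the ribonuclease Ear2 (-5.57 ± 0.47) and the oxysterol hydroxylase Cyp7b1 (-5.53 ± 0.70) were lower as well. Among all 16729 genes the CPM of Lang+ and Lang- libraries did not overlap for 7093, where chance gives 10% with 3 against 3 libraries.

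Of 13 tested cDC2 genes, 0 were higher and 11 lower in Lang+ cells (11 lower adjusted over the list alone, camera adjusted p = 1.85e-08, adjusted p = 0.0260 with an estimated correlation). They included the signal regulatory protein Sirpa (-1.80 ± 0.11), the transcription factor Zeb2 (-3.17 ± 0.24), Mgl2 and the lectin Cd209a (-4.597 ± 0.36). Of 12 class II presentation genes, 11 were lower and 0 higher (11 lower adjusted over the list alone, camera adjusted p = 7.97e-12, adjusted p = 0.143 with an estimated correlation). The class II transactivator Ciita (-2.20 ± 0.12), H2-Ab1 (-2.17 ± 0.13) and the peptide exchange factor H2-DMa (-2.03 ± 0.11) were among them. Of 25 cell cycle genes, 24 were lower and 0 higher (25 lower adjusted over the list alone, camera adjusted p = 7.97e-12, adjusted p = 0.236 with an estimated correlation). Mki67 at 34.8 ± 1.65 against 143 ± 7.72 CPM and the mitotic kinase Aurkb at 5.61 ± 0.783 against 27.3 ± 8.03 CPM were among them. Beside them, 11 of 13 B cell markers were lower and 0 higher in Lang+ cells (12 lower adjusted over the list alone, camera adjusted p = 9.24e-05, adjusted p = 0.294 with an estimated correlation), Blk (-1.15 ± 0.16) and Ms4a1 (-1.22 ± 0.19) among them. Of 15 T cell markers, 2 were lower and 0 higher, with 2 and 0 adjusted over the list alone, and the list itself did not pass (camera adjusted p = 0.715). Its median was 0.05 while its mean, -0.11, and its test pointed lower.

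Costimulation and checkpoint ligands were 8 lower and 1 higher of 12 (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 2.36e-05, adjusted p = 0.143 with an estimated correlation). Cd274, which encodes PD-L1, averaged 71.9 ± 7.23 against 482 ± 61.3 CPM, and the OX40 ligand gene Tnfsf4 averaged 1.32 ± 0.582 against 24.7 ± 1.28 CPM. Cd80 (-2.09 ± 0.12) and Pdcd1lg2, which encodes PD-L2 (-2.31 ± 0.16), were lower too. Of 18 genes of the TSLP and IL-4 pathways 10 were lower and 2 higher (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.00208, adjusted p = 0.143 with an estimated correlation), and Ccl22 was higher (0.38 ± 0.10). Pattern recognition receptors were 11 lower and 0 higher of 20 (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 4.03e-04, adjusted p = 0.143 with an estimated correlation), with the beta-glucan receptor Clec7a (-2.16 ± 0.24) and the flagellin receptor Tlr5 (-3.26 ± 0.43) lower. Of 11 Langerhans cell genes 6 were higher and 2 lower (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0408, adjusted p = 0.143 with an estimated correlation), the lower ones including Csf1r (-1.76 ± 0.19), and this list did not pass with the replicate block or without Lang+ replicate 2. The list of cDC1 genes did not pass (camera adjusted p = 0.0559), although the chemokine receptor Xcr1 (2.24 ± 0.37) and the adhesion molecule Cadm1 (1.45 ± 0.15) were higher and Wdfy4, needed for cross-presentation, was lower (-1.05 ± 0.16).

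Further lists were lower in Lang+ cells. In the unfolded protein response 11 of 16 were lower (12 lower adjusted over the list alone, camera adjusted p = 1.34e-04, adjusted p = 0.294 with an estimated correlation). In glycolysis 8 of 16 were lower (9 lower adjusted over the list alone, camera adjusted p = 0.00314, adjusted p = 0.294 with an estimated correlation). Among NF-kB targets 8 of 17 were lower (8 lower adjusted over the list alone, camera adjusted p = 0.00399, adjusted p = 0.307 with an estimated correlation). Examples were the chaperone Calr (-0.73 ± 0.10), the glucose transporter Slc2a3 (-2.66 ± 0.16), Nfkbiz (-3.10 ± 0.14) and Ptgs2, which encodes cyclooxygenase 2 (-1.69 ± 0.20). Chemokines were 8 lower and 2 higher of 17 (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.307 with an estimated correlation). Ccl9 (-3.12 ± 0.24) was among them. Chemokine receptors were 9 lower of 16 (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00492, adjusted p = 0.143 with an estimated correlation). Ccr6 (-1.497 ± 0.13) was among them. Retinoic acid and TGF-beta genes were 5 lower and 1 higher of 12 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0180, adjusted p = 0.143 with an estimated correlation), and the integrin gene Itgb8 was higher (2.32 ± 0.20). Markers of other cells moved with them: monocyte and macrophage markers were 9 lower and 1 higher of 16 (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.00356, adjusted p = 0.294 with an estimated correlation). Cd68 (-1.61 ± 0.15) and Lyz2 (-1.45 ± 0.18) were among the lower genes. Plasmacytoid markers were 5 lower of 10 (5 lower adjusted over the list alone, camera adjusted p = 0.00482, adjusted p = 0.294 with an estimated correlation). Tcf4 (-2.03 ± 0.12) and Spib (-2.37 ± 0.21) were among them. Plasma cell markers were 5 lower of 10 (6 lower adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.238 with an estimated correlation). Mzb1 (-2.45 ± 0.38) was among them. Resident dendritic cell markers were 6 lower and 2 higher of 10 (3 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0130, adjusted p = 0.156 with an estimated correlation). Dpp4 (-2.82 ± 0.15) was among them.

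The same comparison within treated mice gave 3751 genes with MC903 (1790 higher and 1961 lower in Lang+ cells) and 4953 with OVA (2283 higher and 2670 lower). With MC903 the teneurin Tenm2 had no count in Lang- libraries and was at least 381-fold higher in Lang+ cells. Adra1a averaged 26.3 ± 3.37 against 0.0156 ± 0.0270 CPM and Tcim 12.5 ± 1.23 against 0.0156 ± 0.0270 CPM, with Lang+ first, and Tjp1 (7.61 ± 0.54) and Pkp1 (7.45 ± 0.73) were higher. Nrep (-5.40 ± 0.38), Stra6l (-5.16 ± 0.45), Tnfsf4 (-5.11 ± 0.20), the metalloprotease Adamts7 (-4.81 ± 0.89) and Gfra2 (-4.59 ± 0.24) were lower. The CCR4 ligands Ccl17 (1.05 ± 0.21) and Ccl22 (0.96 ± 0.10) were higher in Lang+ cells with MC903, and Vdr (-1.61 ± 0.21) and Pdcd1lg2 (-1.69 ± 0.15) were lower. Class II presentation genes were 11 lower and 0 higher of 12 (11 lower adjusted over the list alone, camera adjusted p = 4.07e-15, adjusted p = 0.0672 with an estimated correlation). Ciita (-2.62 ± 0.12) and H2-Ab1 (-2.52 ± 0.13) were among them. Of 13 cDC2 genes 12 were lower and 0 higher (13 lower adjusted over the list alone, camera adjusted p = 2.54e-08, adjusted p = 0.0255 with an estimated correlation). Zeb2 (-2.33 ± 0.23) and Mgl2 (-3.33 ± 0.36) were among them.
With OVA, Cd207 averaged 77.7 ± 7.92 against 0.0287 ± 0.0498 CPM, Lang+ first, and Tcim (9.10 ± 0.42), Tnfaip8l3 (7.90 ± 0.58), Pcsk6 (7.66 ± 0.82) and Tcerg1l (7.61 ± 0.33) were higher in Lang+ cells. Nrep (-7.14 ± 0.48), Dkk2 (-5.31 ± 0.33), the collagen receptor Ddr1 (-5.23 ± 0.46), Tnfsf4 (-5.00 ± 0.21) and the lipid carrier Fabp4 (-4.89 ± 0.34) were lower. Class II presentation genes were again 11 lower of 12 (11 lower adjusted over the list alone, camera adjusted p = 4.56e-12, adjusted p = 0.114 with an estimated correlation). Ciita (-2.06 ± 0.12) and H2-Ab1 (-2.24 ± 0.13) were among them. Of cDC2 genes 12 of 13 were lower (13 lower adjusted over the list alone, camera adjusted p = 5.36e-09, adjusted p = 0.0186 with an estimated correlation). Sirpa (-1.72 ± 0.11) and Zeb2 (-2.53 ± 0.23) were among them. Vdr (-2.21 ± 0.23) and Pdcd1lg2 (-3.04 ± 0.16) were lower in Lang+ cells.

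In Lang+ cells MC903 raised proliferation genes, genes of TSLP and IL-4 signalling, CCR4 ligands and the costimulation ligand Cd80, and lowered Cd207, Icosl, Mfge8 and the cDC1 gene Xcr1 (3 libraries per group). T cell markers rose beside the proliferation genes, and for these cycling T cells and cycling Lang+ cells cannot be told apart. Neither the cell cycle list nor the TSLP and IL-4 list passed camera with an estimated correlation. The vitamin D receptor gene Vdr (ENSMUSG00000022479, chromosome 15, 97854425 to 97910630) rose from 6.64 ± 2.24 to 47.0 ± 9.73 CPM. Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036) rose from 52.9 ± 2.94 to 249 ± 5.46 CPM, and Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699) rose from 3883 ± 328 to 11220.0 ± 973 CPM. Icosl, the ligand of the T cell costimulator ICOS (ENSMUSG00000000732, chromosome 10, 78069302 to 78083913), fell from 844 ± 41.6 to 249 ± 24.7 CPM, and Cd207 fell from 89.4 ± 36.0 to 20.6 ± 2.03 CPM. Of 16729 genes 2638 changed, 1502 up and 1136 down, with 450 and 389 at 2-fold or more.

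The largest rises were Mylk, which encodes myosin light chain kinase (3.50 ± 0.21, adjusted p = 2.30e-09), the phospholipase Pla1a (3.20 ± 0.24), the mitotic kinesin Kif2c (3.11 ± 0.54) and the mitotic hyaluronan receptor Hmmr (3.09 ± 0.40). The serotonin receptor Htr7 (2.96 ± 0.26), the kinesin Kif18b (2.92 ± 0.59), cyclin A2 (Ccna2, 2.92 ± 0.50), Stxbp6 (2.87 ± 0.16), Vdr (2.82 ± 0.24) and the IL-2 receptor chain Il2ra (2.81 ± 0.21) followed. The largest falls were the GABA transporter Slc6a13 (-3.98 ± 0.26, adjusted p = 3.69e-09), the nephrin gene Nphs1 (-3.07 ± 0.35), the keratin Krt20 (-3.05 ± 0.31) and the betaine transporter Slc6a12 (-2.72 ± 0.50). Pcsk6 (-2.59 ± 0.53), Scube3 (-2.54 ± 0.16), the autoimmune regulator Aire (-2.46 ± 0.17), the sodium pump subunit Fxyd2 (-2.32 ± 0.17), the lysosomal GTPase Rab7b (-2.18 ± 0.30) and Cd207 (-2.11 ± 0.23) completed them. Cyp24a1, the vitamin D degrading enzyme, had no count in untreated Lang+ libraries and averaged 0.894 ± 1.10 CPM with MC903 (2.15, 0.405 and 0.126 by library), and was not called with a T cell score of each library as a covariate. Its fitted log2 values, 7.38 without and 6.29 with that covariate, depend on the prior count. Over all 16729 genes the libraries of the groups did not overlap in CPM for 5205, and chance gives 10%.

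Of 25 tested cell cycle genes 22 rose and 0 fell (24 higher adjusted over the list alone, camera adjusted p = 2.91e-16, adjusted p = 0.359 with an estimated correlation). Topoisomerase Top2a rose from 17.1 ± 1.70 to 67.5 ± 24.1 CPM, Aurkb rose from 5.61 ± 0.783 to 17.1 ± 3.89 CPM and thymidylate synthase (Tyms) rose from 16.1 ± 1.74 to 33.5 ± 3.56 CPM. Beside them, 11 of 15 T cell markers rose and 0 fell (14 higher adjusted over the list alone, camera adjusted p = 2.86e-05, adjusted p = 0.512 with an estimated correlation). Cd5 (1.45 ± 0.31), Cd28 (1.32 ± 0.29), Lat (1.04 ± 0.23) and Cd4 (0.85 ± 0.20) were among them. With the T cell score as a covariate, chosen after seeing the data, 8 cell cycle genes rose and the median log2 fold change of the list was 0.76, against 22 genes and 1.31 without it. Of 16 glycolysis genes 7 rose and 1 fell (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 9.39e-05, adjusted p = 0.359 with an estimated correlation), lactate dehydrogenase (Ldha, 1.06 ± 0.15) and enolase (Eno1, 0.85 ± 0.11) among the risers.

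Of 18 genes of the TSLP and IL-4 pathways 11 rose and 0 fell (12 higher adjusted over the list alone, camera adjusted p = 1.97e-07, adjusted p = 0.0510 with an estimated correlation). The STAT5-induced suppressor Cish rose from 6.72 ± 0.489 to 40.7 ± 5.50 CPM and Stat5a rose from 166 ± 6.10 to 258 ± 5.05 CPM. Of 12 costimulation and checkpoint ligands 6 rose and 2 fell (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 8.88e-04, adjusted p = 0.373 with an estimated correlation). Cd80 rose from 29.2 ± 2.21 to 130.5 ± 3.09 CPM, Cd274 rose from 71.9 ± 7.23 to 331 ± 27.9 CPM and Pdcd1lg2 rose from 4.17 ± 0.480 to 25.1 ± 1.88 CPM, while Icosl fell by 1.76 on the log2 scale. Tnfsf4 rose (1.44 ± 0.24) to 3.54 ± 0.527 CPM, the Notch ligand Dll4 rose (2.28 ± 0.22), Il6 rose (1.67 ± 0.29) and Il12b, a chain of IL-12, fell (-1.01 ± 0.26). Tnfsf4 held 255 counts over the Lang+ MC903 libraries against 8667 over the Lang- MC903 libraries. A small share of Lang- RNA in the Lang+ libraries could give this rise, which was not tested for this gene. Sirpa (1.30 ± 0.11) and the transcription factor Irf4 (1.15 ± 0.14) rose.

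Of 11 cDC1 genes 4 fell and 1 rose (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0480, adjusted p = 0.373 with an estimated correlation). Xcr1 (-1.87 ± 0.37) and Cadm1 (-0.72 ± 0.14) fell, and the integrin gene Itgae, also carried by T cells, rose (1.16 ± 0.28). The list of 11 Langerhans cell genes, with 3 lower and 1 higher over all genes and 3 and 1 adjusted over the list alone, did not pass (camera adjusted p = 0.221). In it Mfge8 fell from 2858 ± 471 to 759.5 ± 68.9 CPM and Epcam fell from 143 ± 3.91 to 86.8 ± 7.45 CPM, and the endocytic receptor Ly75 rose from 427 ± 70.0 to 889.8 ± 67.6 CPM. Immediate early and dissociation genes, a sign of handling, had 6 of 17 lower (8 lower adjusted over the list alone, camera adjusted p = 0.00115, adjusted p = 0.457 with an estimated correlation). Hspa1a (-1.26 ± 0.26) and Btg2 (-0.80 ± 0.19) were among them. Markers of other cells that moved with MC903 included 4 of 8 neutrophil markers (4 higher adjusted over the list alone, camera adjusted p = 0.0258, adjusted p = 0.359 with an estimated correlation). S100a9 at 5.32 ± 2.71 CPM and Ngp at 7.12 ± 4.6 CPM were among them. Of NK cell markers 3 of 10 rose (3 higher adjusted over the list alone, camera adjusted p = 0.0260, adjusted p = 0.413 with an estimated correlation). Gzmb (2.08 ± 0.40) was among them. Of B cell markers 1 of 13 rose (6 higher adjusted over the list alone, camera adjusted p = 0.00858, adjusted p = 0.648 with an estimated correlation). Cd22 (0.72 ± 0.19) was among them. Of keratinocyte markers 3 of 9 rose (3 higher adjusted over the list alone, camera adjusted p = 0.0481, adjusted p = 0.373 with an estimated correlation), with Krt14 at 1.24 ± 0.180 CPM and no count in untreated libraries, at least 28.0-fold higher.

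The count of 2638 fell to 1004 with the T cell score as a covariate, to 1739 without untreated replicate 1 and to 1752 without MC903 replicate 1, both of the Lang+ population. It was 839 at 2-fold or more and 1398 at an adjusted p under 0.01. The score was 4.941 to 5.127 in untreated and 5.434 to 6.095 in MC903 Lang+ libraries, so the covariate can also take up part of the treatment effect. Cd4, Lat, Cd5 and Cd28 are among the markers that make up the score, so losing their calls is partly built in. With that covariate Cd4 (0.22), Lat (0.23), Itgae (0.29), Cd5 (0.39) and Cd28 (0.42) were not called. Also not called were Cd22 (0.87), Gzmb (1.24), Hspa1a (-0.62), Kif18b (1.66), Slc6a12 (-2.01) and Pcsk6 (-2.002), and the fold of Cd22 was larger with the covariate than without it. Nor was Pcsk6 with DESeq2, Ngp with limma-voom, Cd22 without untreated replicate 1, and Il12b without untreated replicate 1 or MC903 replicate 2 or from these 6 libraries alone. Leaving out 1 library ended the calls of the keratinocyte list in 5 of 6 cases, the cDC1 and NK cell lists in 2 each and the B cell list in 1, the replicate block ended the first 2, and fry the last.

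In Lang- cells MC903 raised Vdr, the Notch ligand Dll4, the costimulation ligands Cd86, Cd80 and Tnfsf4 and TSLP and IL-4 pathway genes, and lowered the cytokines Tnf, Il1b and Il12b and NF-kB targets (3 libraries per group). Neither the TSLP and IL-4 list nor the NF-kB list passed with an estimated correlation, and immediate early and dissociation genes, a sign of handling, fell alongside. Vdr rose from 10.8 ± 1.96 to 143 ± 18.4 CPM. Dll4 (ENSMUSG00000027314, chromosome 2, 119325784 to 119335962) rose from 34.3 ± 11.9 to 260.1 ± 35.3 CPM. The costimulator Cd86 (ENSMUSG00000022901, chromosome 16, 36603869 to 36666081) rose from 234 ± 50.7 to 1037 ± 114 CPM, and Tnfsf4 (ENSMUSG00000026700, chromosome 1, 161395409 to 161418410) rose from 24.7 ± 1.28 to 123 ± 6.47 CPM. Of 16729 genes 2766 changed, 1433 up and 1333 down, with 460 and 575 at 2-fold or more.

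The largest rises were Plek2, a pleckstrin family gene (4.34 ± 0.33, adjusted p = 1.43e-08), Mylk (4.33 ± 0.23), Cgnl1, a cell junction protein (4.12 ± 0.48), and the ubiquitin ligase Neurl1a (4.07 ± 0.39). The actin-binding drebrin gene Dbn1 (4.02 ± 0.23), Adamts7 (4.01 ± 0.84), Pla1a (3.76 ± 0.22), Vdr (3.72 ± 0.24), Ndrg2 (3.59 ± 0.20) and Htr7 (3.37 ± 0.24) followed. The largest falls included the epithelial transcription factor Ehf (-3.82 ± 0.22, adjusted p = 6.62e-10), the adhesion receptor Adgre4 (-3.70 ± 0.27), Calm4 (-3.35 ± 0.27), Slc6a13 (-3.32 ± 0.25) and Fxyd2 (-3.32 ± 0.18). Rgs13 (-3.26 ± 0.68), the clusterin gene Clu (-3.22 ± 0.13), Nuggc (-3.12 ± 0.60) and the neutrophil chemokine Cxcl1 (-3.02 ± 0.35) were also among them. Cyp24a1 averaged 2.42 ± 0.151 against 0.0150 ± 0.0259 CPM, MC903 first, where the untreated value rests on 1 count over 3 libraries (adjusted p = 0.00149). Libraries of the groups did not overlap in CPM for 5601 of all 16729 genes, where chance gives 10%.

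Of 18 TSLP and IL-4 pathway genes 11 rose and 1 fell (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.06e-04, adjusted p = 0.244 with an estimated correlation). Cish rose from 13.7 ± 0.610 to 81.7 ± 1.71 CPM and Ccl22 rose from 2990.0 ± 12.3 to 5773 ± 712 CPM. Stat5a rose from 200.3 ± 1.61 to 303 ± 5.39 CPM. Of 12 costimulation and checkpoint ligands 6 rose and 4 fell, with 6 and 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0502). Cd80 rose from 124 ± 2.07 to 416 ± 24.9 CPM and Pdcd1lg2 rose from 20.7 ± 4.22 to 80.8 ± 8.51 CPM. Of 15 mature migratory dendritic cell genes 4 rose and 3 fell, with 6 and 5 adjusted over the list alone, and Cd200 rose from 161 ± 41.9 to 526 ± 34.8 CPM. That list did not pass (camera adjusted p = 0.550), and its median (-0.01) and mean (0.09) differed in sign.

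Of 17 NF-kB targets 9 fell and 2 rose (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.0128, adjusted p = 0.801 with an estimated correlation). Nfkbiz fell from 899.5 ± 75.5 to 386 ± 47.4 CPM, Ptgs2 fell from 453 ± 52.7 to 165 ± 18.4 CPM and the adhesion molecule Icam1 fell from 1579 ± 201 to 1000 ± 43.6 CPM. Of 16 dendritic cell cytokine genes 7 fell and 2 rose, with 7 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0502). Tnf fell from 121 ± 27.7 to 31.2 ± 7.88 CPM and Il1b fell from 964 ± 206 to 403 ± 86.6 CPM. Il12b fell from 452 ± 47.4 to 185 ± 16.7 CPM. Of 16 unfolded protein response genes 6 fell and 0 rose (6 lower adjusted over the list alone, camera adjusted p = 0.0367, adjusted p = 0.801 with an estimated correlation). Atf3 (-1.38 ± 0.15) and Ddit3 (-0.76 ± 0.17) were among them. Immediate early and dissociation genes fell alongside, 6 of 17 (12 lower adjusted over the list alone, camera adjusted p = 1.06e-04, adjusted p = 0.675 with an estimated correlation). Nr4a1 (-0.68 ± 0.14) and Btg2 (-0.96 ± 0.19) were among them. The interferon-induced GTPase Mx1 fell (-2.40 ± 0.09), as did Aldh1a2 (-1.40 ± 0.26) and Epcam (-1.66 ± 0.13).

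Markers of other cells moved with MC903 here too. Of 13 B cell markers 6 fell and 0 rose (6 lower adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.801 with an estimated correlation). Blk (-0.98 ± 0.16) and Ighm (-0.72 ± 0.16) were among them. Of 10 plasma cell markers 3 fell (6 lower adjusted over the list alone, camera adjusted p = 0.0189, adjusted p = 0.675 with an estimated correlation). Sdc1 (-1.30 ± 0.25) was among them. Of 15 T cell markers 6 rose and 1 fell (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.801 with an estimated correlation). Thy1 rose (2.56 ± 0.28) and Cd8a, which resident cDC1 also carry, fell (-1.32 ± 0.22). The count of 2766 was 1035 at 2-fold or more and 1701 at an adjusted p under 0.01. Leaving out 1 library ended the call of the unfolded protein response in 3 of 6 cases, of B cell markers in 2 and of T cell and plasma cell markers in 1 each, and fry did not call the first 3 of these lists. The plasma cell list did not pass without untreated replicate 2, which held 0.54% immunoglobulin segment counts against 0.298% and 0.259%.

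**Figure D3:**
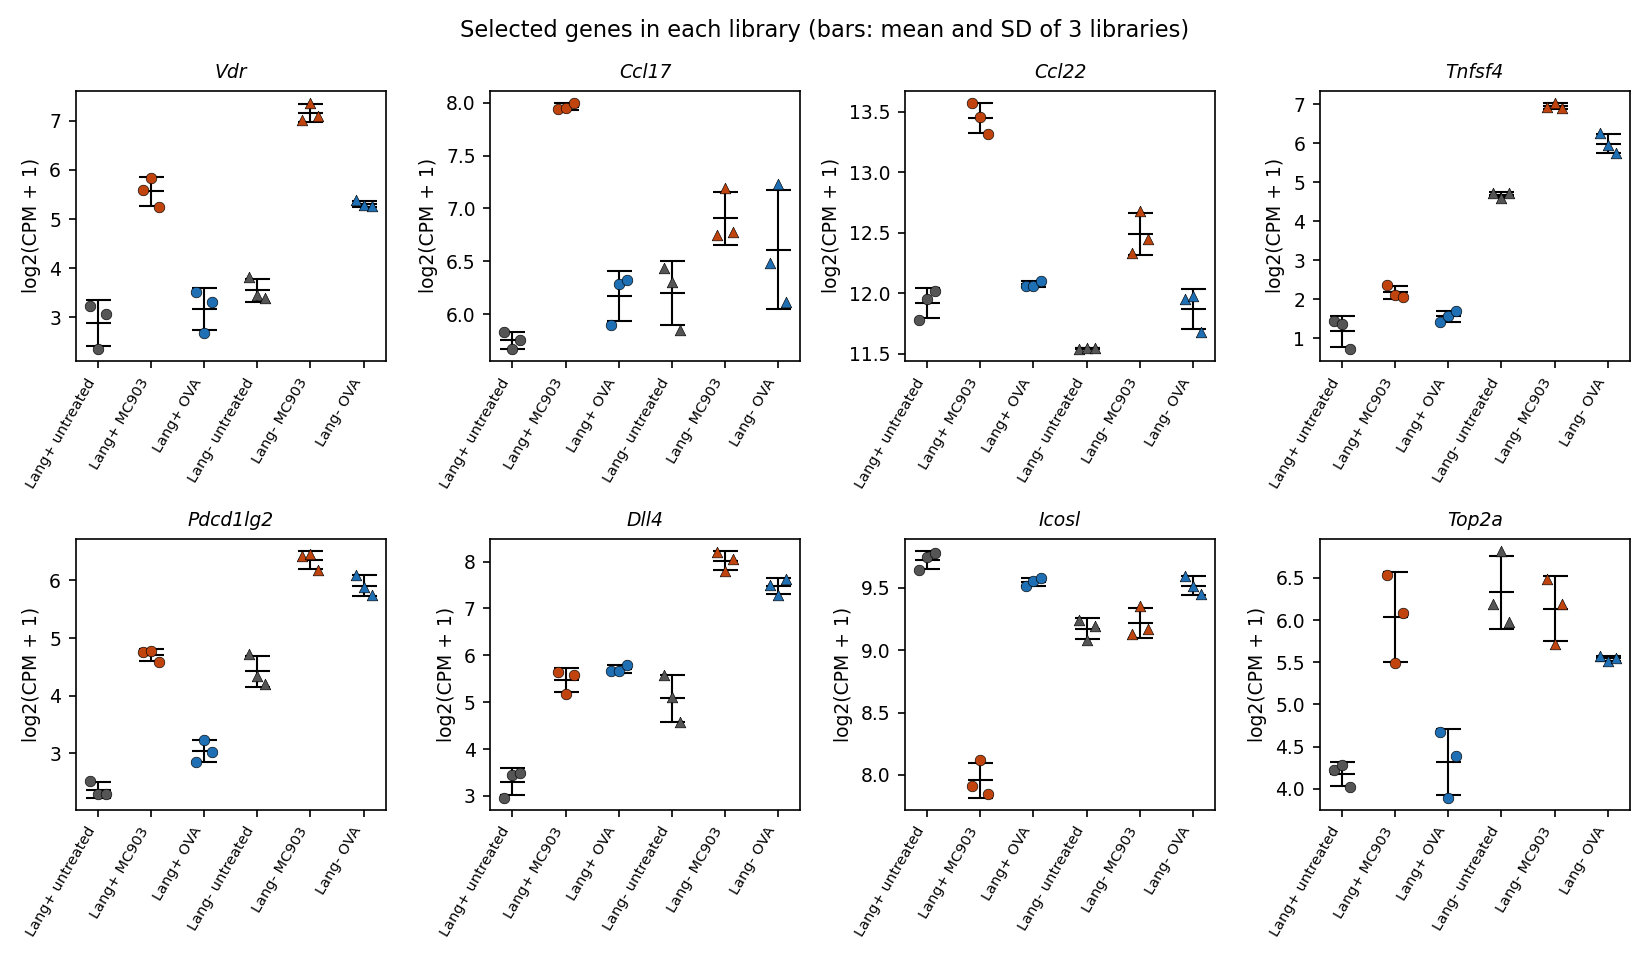
Expression of 8 genes as log2(CPM + 1) on each y axis, which do not start at 0, for the 18 libraries by group on the x axis, with the mean and SD of 3 libraries. Vdr, Ccl22, Pdcd1lg2 and Dll4 were higher with MC903 in both populations, and Icosl fell in Lang+ cells, from 844 ± 41.6 to 249 ± 24.7 CPM.

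In Lang+ cells OVA changed 20 of 16729 genes, 18 up and 2 down (3 libraries per group), and 985 genes had an unadjusted p under 0.05. Dll4 rose from 8.98 ± 1.89 to 51.2 ± 2.84 CPM, Il2ra rose from 8.42 ± 0.617 to 21.0 ± 5.72 CPM and Mylk rose from 15.8 ± 3.94 to 35.2 ± 2.54 CPM. The oxysterol receptor Gpr183, which guides lymphocyte and dendritic cell positioning, rose from 99.5 ± 9.61 to 168 ± 27.1 CPM, and Cd1d1, which presents lipids, rose from 21.7 ± 3.31 to 36.5 ± 3.07 CPM. Cd207 averaged 77.7 ± 7.92 against 89.4 ± 36.0 CPM, OVA first (adjusted p = 0.983).

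The genes that rose at 10 CPM or more were Dll4 (2.51 ± 0.22, adjusted p = 1.22e-05), Stxbp6 (1.501 ± 0.16), Il2ra (1.32 ± 0.21), the chemokine Ccl9 (1.27 ± 0.23), Mylk (1.15 ± 0.20), Gpr183 (0.76 ± 0.11) and Cd1d1 (0.75 ± 0.11). The libraries did not overlap in CPM for 1702 of all 16729 genes, where chance gives 10%. Values that did not pass were Pdcd1lg2 (0.79 ± 0.17, adjusted p = 0.0908), Ccl17 (0.44 ± 0.22, adjusted p = 0.865), Ccl22 (0.15 ± 0.10, adjusted p = 0.943) and Vdr (0.33 ± 0.24, adjusted p = 0.955).

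Some lists passed in Lang+ cells with OVA although 0 of their genes passed alone over all genes. B cell markers tested higher (9 higher adjusted over the list alone, camera adjusted p = 5.35e-08, adjusted p = 0.648 with an estimated correlation). Cd22 was at 0.68 ± 0.19 and Ighd at 0.62 ± 0.19. Cell cycle genes tested higher (0 adjusted over the list alone, camera adjusted p = 3.60e-05, adjusted p = 0.683 with an estimated correlation), where Ccnb1 was at 1.52 ± 0.46. Genes of cDC1 tested lower (3 lower adjusted over the list alone, camera adjusted p = 6.25e-05, adjusted p = 0.137 with an estimated correlation). Snx22 (-1.12 ± 0.28), Wdfy4 (-0.56 ± 0.16) and Naaa (-0.73 ± 0.22) were among them. Cholesterol synthesis genes tested higher (4 higher adjusted over the list alone, camera adjusted p = 7.49e-05, adjusted p = 0.648 with an estimated correlation). The lanosterol synthase gene Lss (0.35 ± 0.11) was among them. Oxidative phosphorylation tested higher (0 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.818 with an estimated correlation). The TSLP and IL-4 pathways did too (1 higher adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.648 with an estimated correlation). Monocyte and macrophage markers tested lower (0 adjusted over the list alone, camera adjusted p = 0.0277, adjusted p = 0.683 with an estimated correlation). On simulated counts of this comparison with changed genes set in advance, edgeR recovered 85% of 2-fold and 99% of 4-fold changes with 5 false calls. That simulation changed 100 genes by each fold and gave every library the untreated Lang+ means. With so many changed genes the adjusted p is less strict than in the real data. The recovery therefore does not show what share of real OVA changes was found. The count of 20 depended on the fit: it was 74 with DESeq2, 5 with limma-voom, 250 with no filter on low counts, 3 from these 6 libraries alone and 12 at an adjusted p under 0.01. It was 8 without untreated replicate 1, 13 without untreated replicate 2, 12 without untreated replicate 3 and 13 without OVA replicate 3. Dll4 and Stxbp6 kept their calls in every fit. Il2ra, Ccl9, Mylk, Gpr183 and Cd1d1 lost theirs from these 6 libraries alone, and Il2ra, Ccl9 and Cd1d1 with limma-voom. Leaving out 1 library ended those of Ccl9 and Mylk in 4 of 6 cases, Il2ra in 3 and Cd1d1 in 2. It also ended the calls of the oxidative phosphorylation and monocyte lists in 3 cases, the TSLP list in 2 and the cell cycle and cholesterol lists in 1, and of the 7 lists named fry called only the cDC1 list.

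In Lang- cells OVA raised Dll4, PD-L2, cholesterol synthesis and class I antigen presentation genes, and lowered the lectin genes Cd209a and Mgl2 (3 libraries per group). Neither the cholesterol synthesis list nor the class I list passed with an estimated correlation, and mitochondrially encoded genes, a measure of RNA quality, fell beside them. Dll4 rose from 34.3 ± 11.9 to 178 ± 20.7 CPM, Pdcd1lg2 (ENSMUSG00000016498, chromosome 19, 29410919 to 29471161) rose from 20.7 ± 4.22 to 59.4 ± 7.54 CPM and Vdr rose from 10.8 ± 1.96 to 38.7 ± 1.84 CPM. Cd209a (ENSMUSG00000031494, chromosome 8, 3743397 to 3748984) and Mgl2 fell, Cd209a from 108 ± 12.1 to 22.7 ± 8.95 CPM and Mgl2 from 72.0 ± 16.8 to 16.6 ± 6.78 CPM. Of 16729 genes 1889 changed, 1231 up and 658 down, with 228 and 201 at 2-fold or more.

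The largest rises were the serotonin transporter Slc6a4 (3.04 ± 0.21, adjusted p = 2.64e-08), placental growth factor (Pgf, 2.63 ± 0.40), the collagen Col4a1 (2.51 ± 0.75), the synapsin Syn3 (2.47 ± 0.27) and the planar polarity gene Vangl1 (2.43 ± 0.18). Mylk (2.38 ± 0.22), Dll4 (2.38 ± 0.20), the inositol phosphatase Inpp5j (2.37 ± 0.16), Trim43b (2.33 ± 0.27) and Htr7 (2.33 ± 0.24) followed. The largest falls were the septin Sept3 (-2.52 ± 0.25, adjusted p = 1.96e-06), Cd209e (-2.31 ± 0.42), Cd209a (-2.25 ± 0.31), the corepressor Hr (-2.20 ± 0.38) and Mgl2 (-2.11 ± 0.33). Cd209d (-2.08 ± 0.29), Nuggc (-1.91 ± 0.57), the mannose receptor Mrc1 (-1.89 ± 0.52), the peptide transporter Slc15a2 (-1.77 ± 0.53) and the collagen prolyl hydroxylase P3h2 (-1.65 ± 0.26) completed them. No overlap in CPM between the groups was found for 4384 of all 16729 genes, where chance gives 10%.

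Of 19 cholesterol synthesis genes 12 rose and 0 fell (12 higher adjusted over the list alone, camera adjusted p = 6.14e-08, adjusted p = 0.297 with an estimated correlation). Mevalonate kinase (Mvk) rose from 26.03 ± 4.43 to 54.9 ± 3.74 CPM, squalene synthase (Fdft1) rose from 73.1 ± 4.2 to 123 ± 15.4 CPM, and Mvd (0.80 ± 0.12) and squalene epoxidase (Sqle, 0.60 ± 0.10) rose. Of 11 class I presentation genes 7 rose and 0 fell (7 higher adjusted over the list alone, camera adjusted p = 2.27e-06, adjusted p = 0.297 with an estimated correlation). The peptide transporter genes Tap1 (0.60 ± 0.08) and Tap2 (0.69 ± 0.08) and the immunoproteasome subunits Psmb8 (0.73 ± 0.11) and Psmb9 (0.72 ± 0.10) rose. Of 24 type I interferon response genes 8 rose and 1 fell (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0164, adjusted p = 0.624 with an estimated correlation), with Stat2 (0.55 ± 0.09) and Xaf1 (0.80 ± 0.16) up and Mx1 (-0.43 ± 0.08) down. Of 15 mature migratory dendritic cell genes 7 rose and 0 fell (9 higher adjusted over the list alone, camera adjusted p = 1.20e-04, adjusted p = 0.297 with an estimated correlation). Socs2 (0.76 ± 0.08), Cd200 (1.12 ± 0.20), the actin bundler Fscn1 (0.48 ± 0.10) and Anxa3 (0.46 ± 0.07) were among them.

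Of 12 costimulation and checkpoint ligands 4 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.566 with an estimated correlation). Cd86 rose from 234 ± 50.7 to 562 ± 70.9 CPM and Tnfsf4 rose from 24.7 ± 1.28 to 63.0 ± 11.2 CPM, and Tnfsf9, the 4-1BB ligand gene, fell (-0.89 ± 0.18). Of 18 TSLP and IL-4 pathway genes 5 rose and 0 fell (5 higher adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.297 with an estimated correlation). Of 25 cell cycle genes 3 fell and 0 rose (3 lower adjusted over the list alone, camera adjusted p = 0.00436, adjusted p = 0.727 with an estimated correlation). Mki67 (-1.12 ± 0.20) and Aurkb (-0.88 ± 0.22) were among them, but without untreated replicate 2 Aurkb was at -0.61 and not called, and the list did not pass. Of 12 retinoic acid and TGF-beta genes 2 fell (2 lower adjusted over the list alone, camera adjusted p = 0.0268, adjusted p = 0.297 with an estimated correlation), Aldh1a2 (-0.99 ± 0.25) and the retinoid receptor Rxra (-0.82 ± 0.15). Oxidative phosphorylation genes had 3 of 29 higher (3 higher adjusted over the list alone, camera adjusted p = 0.00524, adjusted p = 0.727 with an estimated correlation). Beside them, 5 of 8 mitochondrially encoded genes, a measure of RNA quality, fell (5 lower adjusted over the list alone, camera adjusted p = 0.00900, adjusted p = 0.624 with an estimated correlation). The count of 1889 was 1072 without OVA replicate 1, 429 at 2-fold or more and 917 at an adjusted p under 0.01. Leaving out 1 library ended the calls of Nuggc and Slc15a2 in 5 of 6 cases, Col4a1 in 4, Mrc1 in 3 and Aldh1a2 in 2. Those of Col4a1, Mrc1 and Slc15a2 ended from these 6 libraries alone, and that of Col4a1 with the replicate block. Among lists, leaving out 1 library ended the call of retinoic acid and TGF-beta genes in 3 cases, of oxidative phosphorylation, costimulation and interferon genes in 2 each and of mitochondrially encoded genes in 1. With fry the cell cycle, oxidative phosphorylation and mitochondrially encoded lists did not pass.

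**Figure D4:**
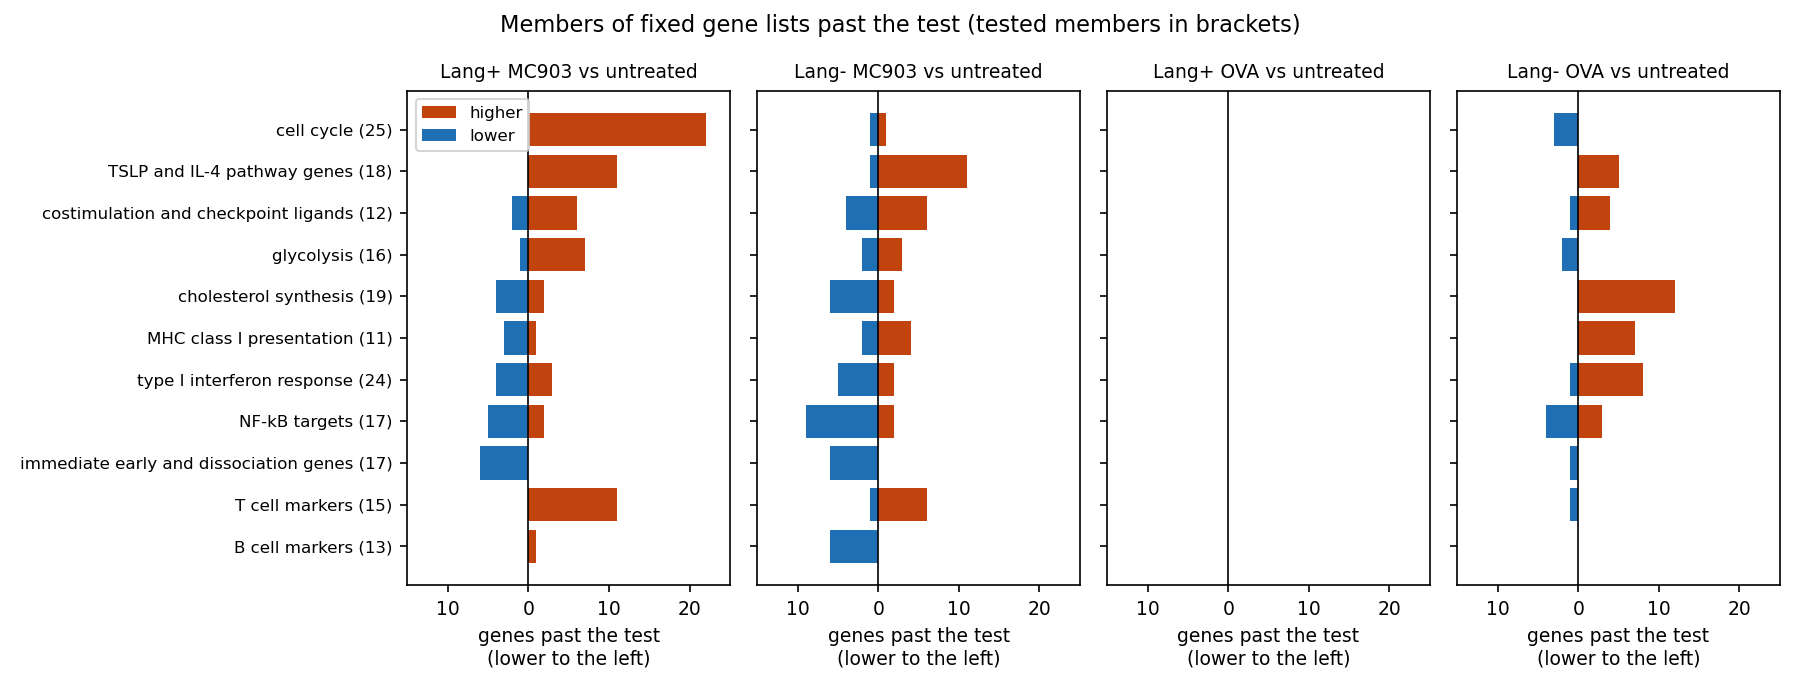
Members of 11 gene lists fixed in advance that passed the test, on the x axis, with higher genes to the right and lower genes to the left of 0, each panel 1 treatment against untreated cells of 1 population, and tested members in brackets. Cell cycle genes had 22 higher in Lang+ cells with MC903, and no gene of these lists passed in Lang+ cells with OVA.

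The 2 treatments were compared directly within each population.
In Lang+ cells 2041 genes differed between MC903 and OVA, 1085 higher and 956 lower with MC903. The cell adhesion gene Nrcam (3.03 ± 0.45), Vdr (2.49 ± 0.23), Pla1a (2.49 ± 0.22), the mitotic kinesin Kif11 (2.43 ± 0.46) and Mylk (2.35 ± 0.20) were higher. Slc6a13 (-3.69 ± 0.26), Fcrlb (-2.85 ± 0.29), Nphs1 (-2.81 ± 0.35), Krt20 (-2.71 ± 0.30) and Pcsk6 (-2.51 ± 0.53) were lower. Ccl17 (1.80 ± 0.22) and Ccl22 (1.38 ± 0.10) were higher with MC903 and Cd207 lower (-1.91 ± 0.23). Of 18 TSLP and IL-4 pathway genes 8 were higher (10 higher adjusted over the list alone, camera adjusted p = 2.87e-06, adjusted p = 0.0947 with an estimated correlation), Cish (2.12 ± 0.16) among them. Of 25 cell cycle genes 20 were higher (21 higher adjusted over the list alone, camera adjusted p = 3.21e-12, adjusted p = 0.374 with an estimated correlation), Top2a (1.79 ± 0.27) among them. Beside them 4 of 15 T cell markers were higher (10 higher adjusted over the list alone, camera adjusted p = 1.24e-04, adjusted p = 0.524 with an estimated correlation). The count of 2041 was 1115 with the T cell score as a covariate, 1177 without MC903 replicate 1, 1353 without MC903 replicate 3, 595 at 2-fold or more and 965 at an adjusted p under 0.01. Pcsk6 was not called with DESeq2 or with that covariate.
In Lang- cells 1711 genes differed, 688 higher and 1023 lower with MC903. The eosinophil chemokine Ccl24 (3.40 ± 0.73), Casc1 (2.98 ± 0.55), Egfl6 (2.69 ± 0.73), Dbn1 (2.67 ± 0.21) and Cish (2.27 ± 0.15) were higher. Fxyd2 (-3.35 ± 0.18), Calm4 (-2.87 ± 0.27), Clu (-2.76 ± 0.12), Adgre4 (-2.76 ± 0.26) and Fcrlb (-2.58 ± 0.29) were lower. Vdr (1.88 ± 0.22) and Tnfsf4 (0.96 ± 0.16) were higher with MC903. Of 19 cholesterol synthesis genes 13 were lower with MC903 (16 lower adjusted over the list alone, camera adjusted p = 6.40e-12, adjusted p = 0.306 with an estimated correlation). Hmgcs1 (-0.84 ± 0.10) and Fdft1 (-0.81 ± 0.10) were among them. Of 11 class I presentation genes 7 were lower (10 lower adjusted over the list alone, camera adjusted p = 5.68e-06, adjusted p = 0.306 with an estimated correlation). H2-D1 (-0.56 ± 0.10) and B2m (-0.51 ± 0.10) were among them. Of 24 type I interferon response genes 9 were lower and 2 higher (2 higher and 13 lower adjusted over the list alone, camera adjusted p = 2.03e-04, adjusted p = 0.371 with an estimated correlation), with Mx1 (-1.97 ± 0.08) and Rsad2 (-1.25 ± 0.15) lower. Beside them, 2 of 15 T cell markers were higher with MC903 (2 higher adjusted over the list alone, camera adjusted p = 0.00209, adjusted p = 0.645 with an estimated correlation). The count of 1711 was 1137 without MC903 replicate 1, 1055 without MC903 replicate 3, 1074 without OVA replicate 2, 500 at 2-fold or more and 856 at an adjusted p under 0.01. Egfl6 was not called with DESeq2 or on leaving out 1 library in 4 of 6 cases, and Ccl24 not with limma-voom or from these 6 libraries alone.

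Whether a treatment acted differently in the 2 populations was tested as an interaction, the change in Lang+ minus the change in Lang- cells. For MC903 824 genes differed, 446 with the more positive change in Lang+ and 378 in Lang- cells. The change in Lang+ cells was the more positive for Kif2c (3.41 ± 0.71), Kif18b (3.41 ± 0.77), the extracellular superoxide dismutase Sod3 (3.39 ± 0.21), Hmmr (3.31 ± 0.53) and Cd209e (3.17 ± 0.73). It was the more negative for Cgnl1 (-4.57 ± 0.64), Dbn1 (-4.01 ± 0.31), Gprin2 (-3.68 ± 0.34), Aif1l (-3.20 ± 0.28) and Atp8b1 (-7.03 ± 1.30), the last a fitted value that depends on the prior count, since Atp8b1 had no count in untreated Lang- libraries. Ccl17 (1.52 ± 0.30), Ccl22 (0.58 ± 0.14) and Cd274 (1.38 ± 0.17) rose more in Lang+ cells, and Icosl differed by -1.81 ± 0.12. Of 25 cell cycle genes 17 had the more positive change in Lang+ cells (22 higher adjusted over the list alone, camera adjusted p = 2.67e-17, adjusted p = 0.334 with an estimated correlation). Mki67 (1.85 ± 0.28) and Aurkb (2.08 ± 0.31) were among them. Beside them, 5 of 13 B cell markers had the more positive change in Lang+ cells (11 higher adjusted over the list alone, camera adjusted p = 3.91e-07, adjusted p = 0.334 with an estimated correlation). Blk (1.144 ± 0.23) was among them. Of 17 chemokines 7 did so (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.73e-05, adjusted p = 0.334 with an estimated correlation). Ccl9 (2.84 ± 0.32) was among them. The count of 824 was 1343 with no filter on low counts, 1238 with DESeq2, 537 without Lang+ MC903 replicate 1, 544 without Lang- MC903 replicate 2, 439 at 2-fold or more and 335 at an adjusted p under 0.01. Cd209e was not called with limma-voom or without Lang+ MC903 replicate 2, and Ccl22 not without MC903 replicate 1 of either population.
For OVA 250 genes differed, 64 with the more positive change in Lang+ and 186 in Lang- cells. The change in Lang+ cells was the more positive for Hr (2.28 ± 0.54), Sept3 (2.18 ± 0.34), Gfra2 (2.00 ± 0.38), Myrip (1.96 ± 0.40) and Dab2 (1.74 ± 0.42). It was the more negative for Plek2 (-3.17 ± 0.42), Vangl1 (-2.39 ± 0.24), Slc6a4 (-2.18 ± 0.27), Inpp5j (-2.15 ± 0.22) and Aif1l (-2.14 ± 0.28). It was also the more negative for Vdr (-1.51 ± 0.33) and Cd86 (-0.88 ± 0.19). Of 11 class I presentation genes 4 had the more negative change in Lang+ cells (6 lower adjusted over the list alone, camera adjusted p = 8.32e-06, adjusted p = 0.606 with an estimated correlation). Tap1 (-0.58 ± 0.11) and Tap2 (-0.65 ± 0.11) were among them. The cell cycle list tested higher with 0 of 25 genes past the test over all genes (10 higher adjusted over the list alone, camera adjusted p = 8.09e-08, adjusted p = 0.606 with an estimated correlation). B cell markers tested higher too, with 0 of 13 past it (9 higher adjusted over the list alone, camera adjusted p = 7.01e-06, adjusted p = 0.606 with an estimated correlation). The count of 250 was 780 with no filter on low counts, 628 with DESeq2, 410 with treatment by number as the replicate block, 148 from the 12 libraries alone, 110 at 2-fold or more and 69 at an adjusted p under 0.01. It was 139 without Lang+ OVA replicate 1, 144 without Lang- untreated replicate 2 and 117 without Lang- OVA replicate 1. With limma-voom Hr, Gfra2, Myrip, Dab2 and Vdr were not called, and from the 12 libraries alone Dab2 and Vdr were not. Leaving out 1 library ended the call of Dab2 in 10 of 12 cases, Hr in 9, Vdr in 5, Cd86 in 4 and Myrip in 1, and the replicate block ended that of Dab2. The cell cycle list did not pass with fry.

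Calls were shared between treatments and between populations. In Lang- cells MC903 and OVA raised 650 genes in common, against 105.45 for unrelated sets, and lowered 337 in common, against 52.43, while 41 genes moved in opposite directions. The log2 fold changes of the 2 treatments had a covariance of 0.404 across genes, against a mean of 0.0788 in 20 simulations of unchanged groups set against the same untreated libraries. Pearson's r across genes, which are not independent, was 0.597 against a simulated 0.496. In Lang+ cells all 18 genes raised by OVA were also raised by MC903, against 1.62 for unrelated sets, and 0 of the 2 lowered genes were lowered by MC903. That covariance was 0.214 against a simulated mean of 0.0847, while r was 0.415, below the simulated 0.506. Part of each excess over the product of the set sizes may come from the shared untreated libraries. The 2 populations share no libraries, and MC903 raised 598 genes in both, against 128.66, and lowered 547 in both, against 90.52, with 57 in opposite directions. OVA raised 13 genes in both populations, against 1.32. Same-number libraries gave a hint of pairing between the 2 populations, so these may not be independent. At an adjusted p under 0.01 the shared genes numbered 387 raised and 133 lowered in Lang- cells, 11 raised in Lang+ cells, and 321 raised and 290 lowered by MC903 in both populations.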

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

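Of the tests in this part, those of normalization, of Lang- cells in the gate, of dilution and of fewer cDC1-like cells were chosen only after the result was seen, as was the T cell score covariate.

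Genes whose response to a treatment differed between Lang+ and Lang- cells by the interaction test numbered 824 for MC903. For proliferation genes the change was the more positive in Lang+ cells: Kif2c (3.41), Kif18b (3.41), Hmmr (3.31), Aurkb (2.08) and Mki67 (1.85). The same direction held for Sod3 (3.39), Cd209e (3.17), the chemokines Ccl9 (2.84), Ccl17 (1.52) and Ccl22 (0.58), Cd274 (1.38) and the B cell kinase Blk (1.144). The opposite direction held for Cgnl1 (-4.57), Dbn1 (-4.01), Gprin2 (-3.68), Aif1l (-3.20), Icosl (-1.81) and Atp8b1 (-7.03), whose fitted value depends on the prior count. Of 60 splits by treatment within each population 5 gave as many calls, the real one included, and the highest other gave 4098, but this count does not decide whether chance can be excluded. Each of the 4 others kept the libraries of 1 population in their treatment groups and so carries a treatment effect. In the split with 4098 the Lang- labels are exchanged, which adds the MC903 effects of both populations. The 48 splits that mixed treatments in both populations gave at most 1 call. Mixing puts the treatment effect into the spread within groups, so few calls follow by construction and exclude nothing. Cd209e lost its call with limma-voom and on leaving out 1 of 12 libraries, and Ccl22 on leaving out either of 2.
For OVA 250 genes differed. The change was the more positive in Lang+ cells for Hr (2.28), Sept3 (2.18), Gfra2 (2.00), Myrip (1.96) and Dab2 (1.74). It was the more negative for Plek2 (-3.17), Vangl1 (-2.39), Slc6a4 (-2.18), Inpp5j (-2.15), Aif1l (-2.14), Vdr (-1.51), Cd86 (-0.88), Tap2 (-0.65) and Tap1 (-0.58). Here 7 of 60 splits gave as many calls, the real one included, and the highest other gave 1404, and the 6 others likewise kept 1 population intact, so the count leaves open whether chance can be excluded. The 49 splits that mixed both populations gave at most 2, where mixing again puts the treatment effect into the spread within groups. With limma-voom Hr, Gfra2, Myrip, Dab2 and Vdr lost their calls, and leaving out 1 library ended that of Dab2 in 10 of 12 cases, Hr in 9, Vdr in 5, Cd86 in 4 and Myrip in 1.

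T cell markers rose with MC903 in both populations, by a median of 0.86 in Lang+ and 0.71 in Lang- cells, with Lck from 119 ± 12.7 to 219 ± 54.2 CPM, Trac from 71.5 ± 9.21 to 134 ± 29.2 CPM and Cd3e from 38.5 ± 7.12 to 71.7 ± 16.7 CPM in Lang+ cells. With an estimated correlation the list passed in neither population. In Lang- cells most of the 15 markers did not pass as rises over all genes, Cd8a fell, and fry did not call the list. Of the 15 markers 14 were at 10 CPM or more in untreated Lang+ cells, 2 are in another list, and the stain held no T cell marker, although a gate on CD11c and I-A/I-E would remove single T cells. Oxidative phosphorylation genes moved by a median of 0.09 at most, and all tested genes by a median of -0.009 in Lang+ and -0.019 in Lang- cells. TMM centres the bulk of genes by construction, so these medians cannot test the normalization itself. They show that the markers rose relative to most genes. The markers varied together between libraries of a group, with a mean pairwise correlation of 0.765 against 0.0838 at the 95th percentile of 1000 random lists, so RNA of T cells carried along is a candidate source. More T cells bound to dendritic cells in treated mice is a biological reading that stays open and untested.

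Cell cycle genes rose in Lang+ cells with MC903, 22 of 25, and the list did not pass with an estimated correlation. Lang- cells inside the Lang+ gate are argued against: genes at least 16-fold higher in Lang- cells need a median share of 0.0605 (quartiles 0 to 0.233), and the cell cycle genes 0.884 (0.802 to 0.922). With the T cell score as a covariate their median log2 change was 0.762 (quartiles 0.351 to 1.25), against 1.31 without it, and 8 rose. Within Lang+ groups cell cycle and T cell scores of the 9 libraries correlated (Pearson's r = 0.916, exact p = 0.00926 over the 216 orders within groups, adjusted 0.0185 over 2 relations; Spearman's rho = 0.883, exact p = 0.0185; r = 0.812 without the 2 farthest). In Lang- cells r was 0.621 (exact p = 0.088, adjusted 0.088), rho 0.5 (exact p = 0.208) and r 0.506 without the 2 farthest. Cycling T cells and cycling Lang+ cells cannot be told apart for these genes, since both scores vary together between these few libraries, and proliferation of Lang+ cells may remain as a hypothesis.

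Cd207 fell in Lang+ cells with MC903 by 2.11 on the log2 scale. Dilution of the gate is argued against as the whole cause, since the 210 other genes at least 16-fold higher in Lang+ cells had a median of -0.56 (quartiles -1.10 to 0.05), with 15 lower and 5 higher by the test. Fewer cDC1-like cells are argued against as the whole cause only by Mfge8 (-1.91) and Epcam (-0.72), Langerhans cell genes that fell too. In the same list Ly75 rose and Cdh1 was not lower (1793 counts untreated, 2027 with MC903), and the list did not pass. The cDC1 list tested lower with the preset correlation, so fewer such cells as part of the cause stay open. A change of Langerhans cells with treatment could account for the falls of Cd207, Mfge8 and Epcam and stays a hypothesis.

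For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each of them 1 split, the real one, gave the largest number of calls. Every other split mixes the 2 groups, which puts their difference into the spread within groups and lowers its calls. The contrast in numbers therefore does not exclude chance. In Lang+ cells MC903 gave 2638 against 2 in the highest other split and OVA 20 against 2. Lang- cells gave 2766 against 0 with MC903 and 1889 against 0 with OVA. Between populations the numbers were 5323 against 2 untreated, 3751 against 0 with MC903 and 4953 against 0 with OVA. Between treatments they were 2041 against 0 in Lang+ and 1711 against 1 in Lang- cells.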

How the results depend on the processing

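The T cell score covariate was chosen after seeing the data, and the other tests here were set before.

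With an absolute log2 fold change of at least 1 besides, calls were 839 in Lang+ and 1035 in Lang- cells with MC903, 429 in Lang- cells with OVA, 2389, 1754 and 2173 between populations untreated, with MC903 and with OVA, 595 and 500 between treatments in Lang+ and Lang- cells, and 439 and 110 in the MC903 and OVA interactions. Fewer genes can pass such a threshold by its construction, as with an adjusted p under 0.01. That one gave 1398 and 12 in Lang+ cells with MC903 and OVA, 1701 and 917 in Lang- cells, 3546 and 3249 between populations untreated and with OVA, 965 and 856 between treatments, and 335 and 69 in the interactions. Shared calls under it were 11, 387 and 133, 321 and 290.

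The T cell score covariate gave 1004 calls in Lang+ cells with MC903 and 1115 between treatments in Lang+ cells. No filter on low counts gave 250 for Lang+ OVA and 1343 and 780 for the MC903 and OVA interactions. The DESeq2 Wald test gave 74, 1238 and 628 for the same results. limma-voom gave 5 for Lang+ OVA. The compared groups alone gave 3 for Lang+ OVA and 148 for the OVA interaction, and a block of treatment by number gave 410 for that interaction. An estimated correlation left 3 of 127 list calls. For these settings the cause was not tested.

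Leaving out 1 library gave 1739 to 2354 calls for Lang+ MC903 (1739 without untreated replicate 1, 1752 without MC903 replicate 1) and 8 to 21 for Lang+ OVA (8, 13 and 12 without untreated replicates 1, 2 and 3, 13 without OVA replicate 3). It gave 2085 to 2335 for Lang- MC903 and 1072 to 2140 for Lang- OVA (1072 without OVA replicate 1). Between populations it gave 4400 to 4809 untreated, 3049 to 3287 with MC903 and 4017 to 4812 with OVA. Between treatments it gave 1177 to 1824 in Lang+ cells (1177 and 1353 without MC903 replicates 1 and 3) and 1055 to 1973 in Lang- cells (1137 and 1055 without MC903 replicates 1 and 3, 1074 without OVA replicate 2). The interactions gave 537 to 808 for MC903 (537 without Lang+ MC903 replicate 1, 544 without Lang- MC903 replicate 2) and 117 to 292 for OVA (139 without Lang+ OVA replicate 1, 144 without Lang- untreated replicate 2, 117 without Lang- OVA replicate 1), and list calls were 120 to 140. The cause was not tested.

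Of 362 called values of named genes, 29 lost the call in some planned or added setting other than leaving out a library or the covariate, 39 on leaving out 1 library and 18 with the covariate, and 0 reversed. The uncalled value of Cd207 in Lang+ OVA against untreated, -0.20, ran from -0.42 without untreated replicate 3 to 0.165 without untreated replicate 1. With a pseudocount of 0.1 the Cd207 differences kept their direction (7.89, 5.79 and 9.30 by treatment, 7.66 over all). With 1 count worth 0.0558 CPM in the library with the smallest normalized size, depth limits folds of genes near 0 counts.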

Other observations

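The regulatory T cell genes in this part were chosen after their values were seen, as were the tests on them.

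Genes of regulatory T cells, some of them also expressed by other activated T cells, rose with MC903 in both populations. In Lang+ cells the lineage factor Foxp3 rose to 42.7 ± 14.7 CPM (2.29 ± 0.39, adjusted p = 5.90e-04), the checkpoint receptor Ctla4 rose from 13.1 ± 3.40 to 80.3 ± 28.1 CPM (2.62 ± 0.42) and Ikzf2 (1.41 ± 0.36) and Icos (1.45 ± 0.26) rose. T cell markers rose beside them, and with the T cell score as a covariate Ikzf2 (0.567) and Icos (0.571) were no longer called, while Foxp3 (1.02) and Ctla4 (1.39) were. Ikzf2 was also not called without untreated replicate 1.
In Lang- cells Foxp3 rose from 7.85 ± 2.25 to 40.7 ± 15.8 CPM (2.38 ± 0.39, adjusted p = 2.98e-04), Ctla4 rose from 17.9 ± 4.52 to 77.9 ± 41.5 CPM (2.12 ± 0.41), Ikzf2 rose (1.83 ± 0.36) and Icos rose from 54.2 ± 11 to 119 ± 39.6 CPM. With the covariate all 4 were called, at 1.41, 1.15, 1.16 and 0.49.
With OVA Foxp3 was at 0.32 ± 0.38 in Lang+ cells (adjusted p = 0.991) and 0.35 ± 0.39 in Lang- cells (adjusted p = 0.639).

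Several innate genes fell with MC903 in both populations. Mx1 was at -1.74 ± 0.08 in Lang+ and -2.40 ± 0.09 in Lang- cells, the profilin receptor Tlr11 at -1.72 ± 0.21 and -2.56 ± 0.21, the inflammasome gene Nlrp3 at -2.40 ± 0.38 and -1.39 ± 0.35, the cytokine Il15 at -0.57 ± 0.09 and -0.72 ± 0.10 and the chemokine Ccl5 at -0.81 ± 0.15 and -1.33 ± 0.15. Ccr4, the receptor of Ccl17 and Ccl22, rose in both (2.60 ± 0.37 and 2.46 ± 0.37). T cell markers rose in the same libraries, and whether the Ccr4 RNA came from T cells or from dendritic cells was not tested. In Lang- cells the complement gene C1qa (1.22 ± 0.29) and the Notch ligand Jag2 (1.15 ± 0.21) rose, and Jag1 fell (-1.01 ± 0.16).

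Of the genes called in Lang+ cells, most had the same sign in Lang- cells, which share no libraries with them. This held for 17 of 20 OVA genes and for 2162 of 2638 MC903 genes (82%). The share over all genes was not computed. Across all tested genes the changes in the 2 populations correlated with Pearson's r of 0.129 for OVA and 0.357 for MC903. Same-number libraries gave a hint of pairing, so the populations may not be independent, and T cell markers rose in both with MC903.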
